A study of Mus musculus with 32 samples.

How the data were processed

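The analysis starts from a pair of deposited tables of read counts per gene, 1 for each cell line, with 1 column per library. The deposited counts are whole numbers that were not normalized, as their differing totals show. The authors used FastQC 0.11.8 and STAR, with mm10 and GRCm38 as genome builds, per the submitters' processing notes. The read counter, its strand setting and the annotation release are not given in the sources used here. Total RNA was taken with TRIzol and libraries were made with NEBNext Ultra II RNA reagents, per the labels' protocols. No unnamed or total line was found in either table, and 0 per-sample columns were left unmapped. The HL-1 table names the columns of the CM libraries DEX, and the labels' descriptions tie these names to titles with CM.

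The AML12 table lists 27843 gene IDs without version, each with at least 1 count, and 99.7% of them are in GENCODE M21. The HL-1 table lists 55414 versioned IDs, 23808 of them without a count, and 94.0% are in M21. The tables were therefore counted on different annotation releases, and some genes have different symbols in them, such as Ctgf in AML12 and Ccn2 in HL-1. Each line was analysed on its own, and the lines were compared by gene ID without version. Positions come from GENCODE M21 on GRCm38. Without a known strand setting, reads of overlapping or antisense genes cannot be told apart, and reads of near-identical paralogs may be split between them.

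Groups come from the labels: cell line, treatment or medium, and time, with 4 libraries each. The genes tested were those kept by edgeR's filterByExpr by group, 14114 in AML12 and 14450 in HL-1. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. The model had 1 mean per group over all 16 libraries of a line. Contrasts were treated against control at each time, the difference of these effects between the times, and the later against the earlier time within each treatment, 10 in all. Calls are at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. The SE of a log2 fold change is its size divided by the root of the F statistic. CPM values use TMM-scaled library sizes.

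Before the data were examined, 35 gene lists were fixed, together with the design, the rule for named genes and most alternatives. Each list was tested with camera on voom values from limma 3.58.1, with a preset correlation of 0.01 and adjustment over the lists with at least 3 tested members. All 35 lists were tested in AML12 and 34 in HL-1. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, whereas fry asks if its own genes move one way on balance. Calls of both lines, from either time, were compared over genes tested in each with Fisher's exact test, two-sided. Genes called at both times were counted with their signs; the times have separate control libraries.

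The rule for named genes applied to each treated against control comparison as follows. Among called genes whose 4 treated libraries all lay above or all below the 4 controls, with at least 1 CPM in a compared group and a symbol that is no predicted or clone name, it took the 8 largest rises and the 8 largest falls. It added the core clock genes, called or not, and up to 4 genes of every other list with the smallest p. For the other contrasts it took 4 rises and 4 falls, the clock genes and up to 2 genes per list. The rule gave 1164 results for single genes, 811 of them called. The text gives 379 of these, 324 of them called, picked after the values were seen. The values of 2 genes that the rule gave are not reported here, while counts of called genes and list tests include them. The identity genes of each line were picked from their lists in the same way.

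The alternatives fixed beforehand were RLE size factors, total counts only, no low-count filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit of only the 8 compared libraries, and leaving out each library in turn. Thinning of all libraries to the lowest total of their line, and a test of the overlap within 10 strata of expression, were added after seeing the data. A ratio against a group with 0 counts is given as a bound against 3 counts over the group. Ratios against 1 to 3 counts have exact 95% intervals. Both cover counting error only, as reads are not independent molecules.

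The tests were tried on simulated counts with the means and library sizes of the real data, with 10 simulations of 200 changed genes. At a log2 change of 0.5 the share of changed genes found was 71% for DEX at 17 h (on 13976 genes) and 77% at 25 h (on 13955). It was 64.9% for CM at 16 h (on 14217) and 70.7% at 28 h (on 14207). For the differences between the times it was 63.5% in AML12 (on 13964) and 67% in HL-1 (on 14214). The time contrasts gave 67.3% in AML12 controls (on 13953) and 79.8% in DEX cells (on 13954). They gave 76.8% in HL-1 controls (on 14228) and 77% in CM cells (on 14204).

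At a log2 change of 1 the shares on the same genes were higher. In the same order they were 93% and 93.9% for DEX, 79.8% and 80.6% for CM. The differences gave 87.8% and 75.8%, and the time contrasts 90%, 92%, 92.7% and 87.9%. Per simulation 1.97% to 7.10% of calls were false. Camera found 10 of 10 raised and called 0 of 200 unchanged lists of 25 genes. Correlated genes were not tested.

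The biological coefficient of variation was 0.0528 in AML12 and 0.0527 in HL-1. Over 48 pairs of libraries of a group, the chi-square per degree of freedom against counting noise was 2.06 to 18.1, so no pair differed by counting noise alone. The 10 most abundant genes took 5.29% to 6.32% of the counts, and mitochondrially encoded genes 1.56% to 2.88%. No file was left out.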

Results

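The series holds 32 RNA-seq libraries made from total RNA of 2 mouse cell lines, in 8 groups of 4. AML12, a hepatocyte line, was sampled as control cells and as cells given a treatment that the labels abbreviate as DEX, each at 17 h and 25 h. HL-1, a cardiomyocyte line, was sampled at 16 h and 28 h in medium taken from AML12 cultures. That was either control medium without DEX synchronization or conditioned medium (CM) with it. The design compares treated with control cells at each time, and the 2 times within each treatment. Total counts per library ranged from 15.0 M (mega) to 17.5 M in AML12 and from 15.7 M to 19.3 M in HL-1. The HL-1 CM libraries were deeper than their controls, at 18.6 ± 0.606 against 16.3 ± 0.722 M at 16 h (mean ± SD, n = 4). At 28 h they held 18.2 ± 0.753 against 16.6 ± 1.00 M. A value after a gene is its log2 fold change ± SE from edgeR's quasi-likelihood test with 4 libraries per group. Expression levels in CPM, counts scaled to the library's TMM-scaled total, are means ± SD of 4 libraries. Genes given as largest rises or falls between treated and control cells had all 4 treated libraries above or all below the 4 controls, and at least 1 CPM in a compared group. Nothing in the labels says that the 4 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

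Both lines expressed part of the programme of their tissue. In AML12 cells the hepatocyte transcription factor Hnf4a averaged 205 CPM over 16 libraries and the lipoprotein gene Apob 154 CPM. Albumin (Alb) averaged 1.43 CPM and the bile duct keratin Krt19 1700.5 CPM. Of 34 hepatocyte genes in the table, 7 reached 10 CPM and 18 lay under 1 CPM. In HL-1 cells the gap junction gene Gja1 averaged 466 CPM, desmin (Des) 524 CPM and the cardiac troponin Tnnt2 34.5 CPM. The mesenchymal genes Vim (6284 CPM) and Col3a1 (1455 CPM) were abundant there. Of 35 sarcomere and natriuretic peptide genes, 5 reached 10 CPM and 25 lay under 1 CPM.

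**Figure D1:**
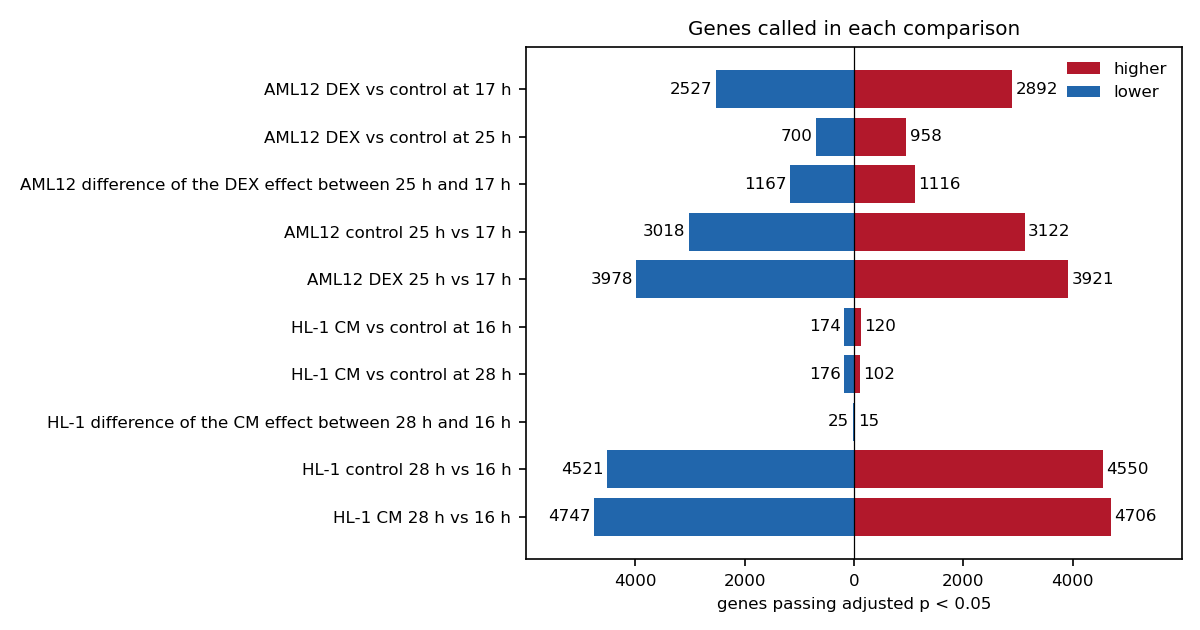
Number of genes passing an adjusted p of 0.05 in each comparison, with genes higher in the first-named group drawn to the right and genes lower in it to the left. The DEX comparison at 17 h had 2892 genes higher and 2527 lower, and the CM comparison at 16 h 120 higher and 174 lower.

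AML12 cells given DEX showed a broad response at 17 h. Zbtb16, a zinc finger transcription factor gene (ENSMUSG00000066687), lies on chromosome 9, 48654297 to 48836222, minus strand, in GRCm38. It went from 0 counts in the 4 controls to 13.1 ± 0.794 CPM, at least 288-fold higher against a floor of 3 counts over the control group. The sulfotransferase Sult1a1 (5.07 ± 0.32), the kinesin Kif17 (4.41 ± 0.35), the plasma protein gene Orm1 (3.67 ± 0.18) and Crispld2 (3.66 ± 0.24) also rose. So did the metalloprotease Tll1 (3.66 ± 0.23), the somatostatin receptor Sstr3 (3.59 ± 0.49) and the crystallin Cryaa (3.25 ± 0.36). The largest falls were in Clca3b (-3.97 ± 0.25), the clock output factor Dbp (-3.88 ± 0.18), the period gene Per3 (-3.22 ± 0.13) and the myosin Myh15 (-3.19 ± 0.40). Next came the GABA receptor subunit Gabrp (-3.09 ± 0.14), the sulfotransferase Chst4 (-2.91 ± 0.22), Vwa5b1 (-2.83 ± 0.24) and the kinase Blk (-2.79 ± 0.29). Dbp (ENSMUSG00000059824) lies on chromosome 7, 45705088 to 45710203, plus strand, and Per3 (ENSMUSG00000028957) on chromosome 4, 151003652 to 151044665, minus strand. In all, 5419 of 14114 tested genes passed, 2892 higher and 2527 lower. Of these, 202 and 315 changed at least 2-fold.

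Of 25 tested glucocorticoid-responsive genes, 17 rose and 3 fell (17 and 5 adjusted over the list alone, camera adjusted p = 4.24e-08, 0.00704 with estimated correlation). They included Sgk1, a kinase of ion transport (2.32 ± 0.07), which went from 57.6 ± 5.77 to 287 ± 20.7 CPM. The chaperone partner Fkbp5 (1.77 ± 0.06), the leucine zipper gene Tsc22d3 (1.73 ± 0.05) and the factor Klf9 (1.23 ± 0.05) rose too. Of 16 tested core clock genes, 5 rose and 9 fell (the same adjusted over the list alone, camera adjusted p = 0.00269, 0.142 with estimated correlation), and the list as a whole moved down. The activator genes Arntl (0.97 ± 0.08) and Clock (0.31 ± 0.05) rose, as did Per1 (1.65 ± 0.07), Nfil3 (0.33 ± 0.06) and Bhlhe41 (0.33 ± 0.10). Per2 (-1.77 ± 0.11), Cry1 (-1.01 ± 0.12), Cry2 (-1.02 ± 0.09) and Nr1d1 (-0.95 ± 0.12) fell. Nr1d2 (-1.63 ± 0.07) and Tef (-2.75 ± 0.06) fell as well. Ciart stood at -0.31 ± 0.24 and Bhlhe40 at -0.10 ± 0.06, with edgeR adjusted p-values of 0.323 and 0.206.

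Proliferation genes moved together at 17 h. Of 30 tested S phase genes, 28 rose and 0 fell (30 and 0 adjusted over the list alone, camera adjusted p = 2.71e-17, 0.0720 with estimated correlation). The ribonucleotide reductase Rrm2 stood at 1.59 ± 0.07. Of 30 tested G2 and mitosis genes, 30 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 8.81e-22, 0.0720 with estimated correlation), with Foxm1 at 0.93 ± 0.07 and Plk1 at 0.87 ± 0.07. Of 24 tested cholesterol synthesis genes, 21 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 4.93e-11, 0.0720 with estimated correlation). Msmo1 (0.65 ± 0.05) and Lss (0.62 ± 0.05) were among them. Of 20 tested fatty acid synthesis and storage genes, 12 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.0110, 0.241 with estimated correlation). Of 30 tested genes of the unfolded protein and integrated stress response, 25 rose and 1 fell (26 and 1 adjusted over the list alone, camera adjusted p = 7.83e-13, 0.0194 with estimated correlation). The amino acid enzymes Psat1 (1.10 ± 0.06) and Asns (0.87 ± 0.05) belong to that list. Of 24 tested ribosome biogenesis genes, 17 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 6.65e-05, 0.148 with estimated correlation).

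Inflammatory genes went the other way. Of 24 tested chemokines and NF-kB targets, 1 rose and 20 fell (1 and 22 adjusted over the list alone, camera adjusted p = 4.92e-15, 0.0467 with estimated correlation). Cxcl5 fell (-1.5 ± 0.05) from 2225 ± 65.2 to 785 ± 35.4 CPM, and Ccl20 (-2.24 ± 0.08) and the prostaglandin synthase Ptgs2 (-1.64 ± 0.08) fell too. Of 26 tested interferon response genes, 1 rose and 12 fell (1 and 14 adjusted over the list alone, camera adjusted p = 0.00269, 0.0467 with estimated correlation), and Irf1 stood at -0.68 ± 0.07. The sarcomere list (0 rose and 5 fell of 11, the same adjusted over the list alone, camera adjusted p = 0.00237, 0.0720 with estimated correlation) also moved down. So did the immune marker list (0 rose and 3 fell of 4, the same adjusted over the list alone, camera adjusted p = 0.0415, 0.173 with estimated correlation). The hepatocyte list went both ways (4 rose and 10 fell of 16, 5 and 10 adjusted over the list alone, camera adjusted p = 0.117). The heme carrier Hpx (-1.52 ± 0.09) and Hnf4a (-0.54 ± 0.04) fell, and haptoglobin (Hp) rose (1.55 ± 0.09). The bile acid receptor Nr1h4 (2.01 ± 0.07), the lipid receptor Ppara (3.00 ± 0.17) and the growth factor gene Ctgf (1.80 ± 0.07) rose, and angiotensinogen (Agt) fell (-2.12 ± 0.22). In total 12 of 35 lists passed camera, and 4 of them with an estimated correlation. Orm1 and Clca3b have close paralogs, which makes their levels uncertain. Replicate 2 of DEX at 17 h stood apart from its group. Its chi-square per degree of freedom against counting noise was 13.6 to 18.1 in pairs with the other 3 libraries, against 2.41 to 4.00 among them. Without it 5569 genes passed. Among the genes named here, leaving out 1 of the 8 libraries ended the call of Bhlhe41 (1 case, adjusted p of 0.0559 without control 17 h replicate 4). Among lists it ended that of immune markers (3 cases, adjusted p up to 0.0758), as did no filter (adjusted p = 0.191).

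At 25 h proliferation genes were higher in AML12 cells given DEX. Of 30 tested S phase genes, 30 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 5.05e-43, 0.0162 with estimated correlation). The replication licensing gene Mcm3 stood at 0.85 ± 0.07 and Rrm2 at 0.92 ± 0.08. Of 30 tested G2 and mitosis genes, 29 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 5.39e-45, 0.0162 with estimated correlation), with Kif20a at 0.75 ± 0.06 and the topoisomerase Top2a at 0.64 ± 0.06. Of 20 tested p53 targets, 0 rose and 8 fell (1 and 12 adjusted over the list alone, camera adjusted p = 4.10e-05, 0.0162 with estimated correlation). The cell cycle inhibitor Cdkn1a (-0.44 ± 0.06) and Phlda3 (-0.37 ± 0.06) were among those that fell. Of 24 tested cholesterol synthesis genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 1.29e-09, 0.0838 with estimated correlation), for example Ebp (0.32 ± 0.04) and Insig1 (0.34 ± 0.06).

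At this time 1658 of 14114 genes passed, 958 higher and 700 lower, and 69 changed at least 2-fold. Replicate 4 of DEX at 25 h stood apart from its group, with a chi-square per degree of freedom of 3.90 to 5.06 with the other 3, against 2.31 to 3.69 among those. Its values lay apart for Rrm2, Alb, Sult1a1 and Nr1d1, among other genes, and without it 1135 genes passed. The largest rises were in Tll1 (2.60 ± 0.34), the collagen Col5a1 (1.76 ± 0.32), Crispld2 (1.70 ± 0.27) and the glutathione transferase Gsta1 (1.53 ± 0.26). Klra4 (1.5 ± 0.34), Sult1a1 (1.43 ± 0.35) and Als2cr12 (1.40 ± 0.30) followed, with albumin (Alb, 1.40 ± 0.27), which went from 0.870 ± 0.347 to 2.35 ± 0.888 CPM. The largest falls were in Clca3b (-2.41 ± 0.15), its family member Clca3a2 (-1.92 ± 0.29), skeletal actin (Acta1, -1.59 ± 0.19) and Blk (-1.56 ± 0.22). The histidine catabolism gene Uroc1 (-1.56 ± 0.31), the kinase Mapkapk3 (-1.52 ± 0.28), the complement inhibitor Serping1 (-1.43 ± 0.26) and the chemokine Ccl5 (-1.40 ± 0.30) fell next. Fkbp5 (0.56 ± 0.06) and Fam107a (1.07 ± 0.16) rose within the glucocorticoid-responsive list, which did not pass as a whole (8 rose and 3 fell of 25, the same adjusted over the list alone, camera adjusted p = 0.225).

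The core clock list did not pass at 25 h either (5 rose and 3 fell of 16, 5 and 4 adjusted over the list alone, camera adjusted p = 0.225). Nr1d1 (0.69 ± 0.10), Dbp (0.66 ± 0.10), Tef (0.51 ± 0.05), Per1 (0.26 ± 0.07) and Nr1d2 (0.22 ± 0.06) rose. Arntl (-0.42 ± 0.09) and Nfil3 (-0.35 ± 0.06) fell. Values that did not pass were 0.07 ± 0.05 for Clock, 0.21 ± 0.10 for Per2, 0.14 ± 0.09 for Per3 and -0.35 ± 0.12 for Cry1. They were -0.03 ± 0.08 for Cry2, 0.02 ± 0.17 for Ciart, -0.07 ± 0.06 for Bhlhe40 and 0.18 ± 0.11 for Bhlhe41. Calls lost without 1 of the 8 libraries were those of Per1 (2 cases, adjusted p up to 0.115 without DEX 25 h replicate 4) and Nr1d2 (6 cases, adjusted p up to 0.107 without control 25 h replicate 2).

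Other lists moved at 25 h. Fatty acid synthesis and storage (11 rose and 1 fell of 20, the same adjusted over the list alone, camera adjusted p = 0.00141, 0.136 with estimated correlation) went up. The stress response list went up (15 rose and 3 fell of 30, 16 and 3 adjusted over the list alone, camera adjusted p = 0.000316, 0.136 with estimated correlation), and so did nuclear-encoded oxidative phosphorylation (1 rose and 0 fell of 37, the same adjusted over the list alone, camera adjusted p = 0.0392, 0.595 with estimated correlation). Secreted hepatokines went down (2 rose and 6 fell of 21, 3 and 8 adjusted over the list alone, camera adjusted p = 0.00141, 0.0162 with estimated correlation). In that list Agt stood at -1.18 ± 0.14 and the retinol carrier Rbp4 at -0.42 ± 0.05. Immediate early genes went down (0 rose and 10 fell of 23, the same adjusted over the list alone, camera adjusted p = 7.67e-06, 0.0920 with estimated correlation), with Egr1 at -0.60 ± 0.10 and Jun at -0.37 ± 0.08. Matrix genes went down (3 rose and 9 fell of 27, 3 and 12 adjusted over the list alone, camera adjusted p = 0.000497, 0.145 with estimated correlation), with tenascin (Tnc) at -1.19 ± 0.09. Autophagy and lysosome genes went down (0 rose and 8 fell of 25, 0 and 9 adjusted over the list alone, camera adjusted p = 0.000283, 0.0162 with estimated correlation), with Tfeb at -0.32 ± 0.06 and Ctsd at -0.16 ± 0.04. The acute-phase list went down (3 rose and 6 fell of 13, 3 and 8 adjusted over the list alone, camera adjusted p = 0.00206, 0.136 with estimated correlation). Within it Hpx fell (-0.66 ± 0.09) and Hp rose (0.63 ± 0.11). Glycolysis and hypoxia genes went down (0 rose and 9 fell of 28, 0 and 10 adjusted over the list alone, camera adjusted p = 5.20e-05, 0.162 with estimated correlation), as did the sarcomere list (1 rose and 3 fell of 11, the same adjusted over the list alone, camera adjusted p = 0.00703, 0.131 with estimated correlation). In total 14 of 35 lists passed, and 5 of them with an estimated correlation. The oxidative phosphorylation call was lost without 1 library (4 cases, adjusted p up to 0.192) and with thinned counts (adjusted p = 0.0803).

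**Figure D2:**
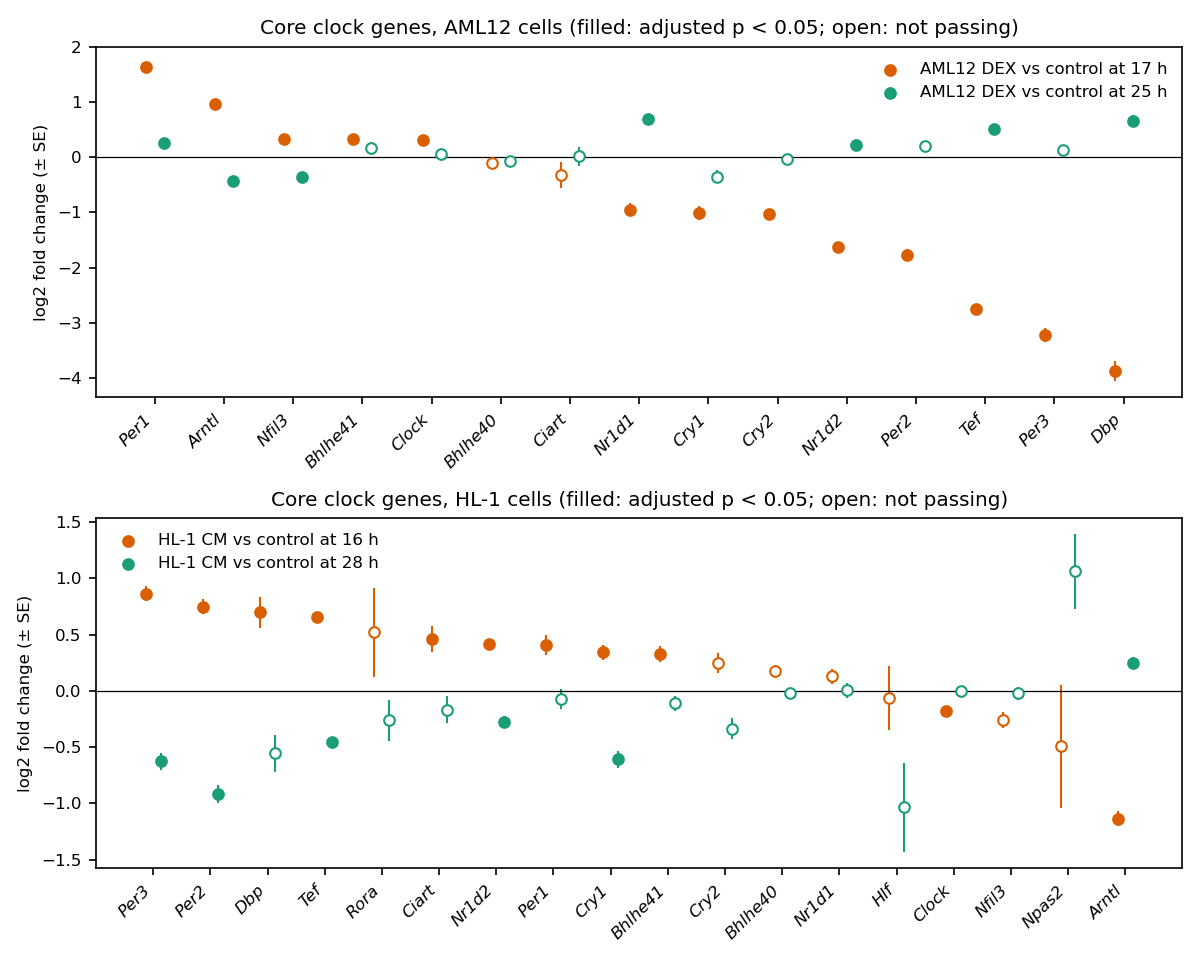
Log2 fold change ± SE of core clock genes for treated against control cells at both times, in AML12 (top) and HL-1 (bottom), with filled points where the adjusted p was under 0.05 and open points where it was not. Dbp stood at -3.88 at 17 h and 0.66 at 25 h in AML12, and Arntl at -1.14 at 16 h and 0.25 at 28 h in HL-1.

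The effect of DEX in AML12 cells differed between the times for 2283 of 14114 genes. The test was of the 25 h effect minus the 17 h effect, which was above 0 for 1116 of these genes and below 0 for 1167. Core clock genes above 0 were Dbp (4.55 ± 0.21), Per3 (3.36 ± 0.16), Tef (3.26 ± 0.08), Per2 (1.98 ± 0.15) and Nr1d2 (1.84 ± 0.10). Nr1d1 (1.64 ± 0.16), Cry2 (0.99 ± 0.12) and Cry1 (0.66 ± 0.17) were above 0 too. Arntl (-1.40 ± 0.12), Per1 (-1.39 ± 0.10), Nfil3 (-0.68 ± 0.09) and Clock (-0.24 ± 0.07) were below 0. The chemokine Ccl3 (3.38 ± 0.80) was among the 4 largest differences above 0. It had 1 count in the 4 DEX libraries of 17 h, so its fitted value depends on the prior count. Of 25 tested glucocorticoid-responsive genes, 1 rose and 14 fell (the same adjusted over the list alone, camera adjusted p = 5.41e-13, 0.000610 with estimated correlation), meaning above and below 0 here. Sgk1 (-2.32 ± 0.10) and Tsc22d3 (-1.53 ± 0.07) were below 0. So were Sstr3 (-4.26 ± 1.08), Sult1a1 (-3.64 ± 0.58), Kif17 (-3.56 ± 0.83), the glycosyltransferase Extl1 (-3.18 ± 0.36), Nr1h4 (-1.76 ± 0.10) and Ctgf (-1.70 ± 0.10).

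In the same test chemokines and NF-kB targets had a more positive effect at 25 h (camera adjusted p = 3.11e-18, 0.0347 with estimated correlation). Ccl20 stood at 2.42 ± 0.11 and Cxcl5 at 1.39 ± 0.07. Interferon genes did too (camera adjusted p = 0.00363, 0.0487 with estimated correlation), with Irf1 at 0.59 ± 0.09 and Gbp2 at 1.32 ± 0.22. The stress list had a more negative effect (camera adjusted p = 7.60e-10, 0.0347 with estimated correlation), with Atf4 at -0.71 ± 0.07 and Herpud1 at -0.68 ± 0.07. In total 11 of 35 lists passed camera, 4 of them with an estimated correlation. Bhlhe40 (0.03 ± 0.08), Bhlhe41 (-0.15 ± 0.15) and Ciart (0.33 ± 0.29) did not pass. Calls lost without 1 of the 16 libraries were those of Sstr3 (1 case, adjusted p of 0.0605 without control 25 h replicate 4) and Clock (1 case, adjusted p of 0.0507 without control 17 h replicate 2). Total counts only ended that of Clock (adjusted p = 0.0568). With total counts as the only scaling the share of calls above 0 moved from 48.9% to 62.2%.

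In AML12 cells 1321 genes passed at both times, against 637 for independent lists, and 94.2% of them had the same sign. Of 8 core clock genes called at both times, 6 had opposite signs. Across genes, which are not independent replicates, the log2 fold changes of the 2 times had a Pearson correlation of 0.524 and a Spearman correlation of 0.401.

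AML12 cells differed between the times. Between 17 h and 25 h in control cells, of 30 tested S phase genes, 0 rose and 29 fell (the same adjusted over the list alone, camera adjusted p = 4.23e-14, 0.169 with estimated correlation). Mcm3 stood at -0.80 ± 0.07. Of 30 tested G2 and mitosis genes, 0 rose and 30 fell (the same adjusted over the list alone, camera adjusted p = 1.14e-18, 0.169 with estimated correlation), with Ccnb1 at -0.97 ± 0.06. Of 24 tested chemokines and NF-kB targets, 19 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 4.50e-09, 0.169 with estimated correlation), with the growth factor Csf1 at 0.98 ± 0.05 and Nfkbia at 1.05 ± 0.06. Of 24 tested cholesterol synthesis genes, 0 rose and 18 fell (the same adjusted over the list alone, camera adjusted p = 3.14e-07, 0.186 with estimated correlation). Tm7sf2 (-0.73 ± 0.05) and Dhcr7 (-0.48 ± 0.05) were among them. Single genes with the largest rise were Acta1 (2.36 ± 0.22), the immediate early gene Egr1 (2.14 ± 0.12), calponin (Cnn1, 1.91 ± 0.16) and the matrix gene Chad (1.81 ± 0.17). Those with the largest fall were Apol8 (-3.44 ± 0.45), Lrrn4cl (-1.99 ± 0.36), the cystine transporter Slc7a11 (-1.97 ± 0.09) and Lgr5 (-1.79 ± 0.28).

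In DEX cells Dbp (4.60 ± 0.17), Cnn1 (3.32 ± 0.22), Per3 (3.23 ± 0.13) and Endou (3.18 ± 0.23) rose most between 17 h and 25 h. Zbtb16 (-5.82 ± 0.19), Extl1 (-4.42 ± 0.19), Sstr3 (-3.86 ± 0.51) and Apol8 (-3.46 ± 0.45) fell most. Sgk1 (-3.15 ± 0.07) and Fkbp5 (-1.31 ± 0.05) fell, and the chemokine Ccl20 (3.02 ± 0.08) and the adhesion gene Vcam1 (2.28 ± 0.06) rose. The proliferation genes Rrm2 (-1.36 ± 0.07) and Ccnb1 (-0.96 ± 0.06) fell. The stress genes Slc7a11 (-2.25 ± 0.08) and Asns (-1.28 ± 0.05) fell too, as did the cholesterol genes Mvk (-0.91 ± 0.05) and Lss (-0.78 ± 0.05). These time contrasts passed for 6140 genes in control cells (3122 higher and 3018 lower at 25 h) and 7899 in DEX cells (3921 higher and 3978 lower). For control cells 13 of 35 lists passed camera, 0 of them with an estimated correlation, and for DEX cells 14 of 35 lists passed camera, 0 of them with an estimated correlation.

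Over the same interval clock genes of control AML12 cells moved both ways. Per1 (0.5 ± 0.07), Bhlhe40 (0.37 ± 0.06), Ciart (1.12 ± 0.19), Nfil3 (0.30 ± 0.06) and Nr1d1 (0.34 ± 0.11) rose. Tef (-0.59 ± 0.05) and Cry1 (-0.35 ± 0.11) fell. Nr1d2 (0.12 ± 0.06), Per2 (-0.18 ± 0.10), Clock (0.08 ± 0.05) and Per3 (-0.13 ± 0.09) did not pass. Cry2 (-0.06 ± 0.08), Dbp (0.05 ± 0.11), Arntl (-0.03 ± 0.09) and Bhlhe41 (-0.03 ± 0.11) did not pass either. In DEX cells Tef (2.66 ± 0.06), Nr1d2 (1.97 ± 0.07), Nr1d1 (1.98 ± 0.11) and Per2 (1.79 ± 0.11) rose. Cry2 (0.93 ± 0.09), Ciart (1.45 ± 0.20), Bhlhe40 (0.39 ± 0.06) and Cry1 (0.31 ± 0.13) rose as well. Arntl (-1.43 ± 0.09), Per1 (-0.89 ± 0.06), Nfil3 (-0.38 ± 0.06) and Clock (-0.16 ± 0.05) fell. Bhlhe41 (-0.18 ± 0.10) did not pass. The labels give no harvest date, so a harvest effect is not separable from time. With total counts as the only scaling, the higher share in control cells moved from 50.8% to 39.5%. In DEX cells the call lost without 1 of the 8 libraries was that of Cry1 (7 cases, adjusted p up to 0.218 without DEX 25 h replicate 3). It also ended with RLE size factors, total counts only, limma-voom, DESeq2, only 8 libraries and thinned counts (adjusted p of 0.0512 to 0.106).

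HL-1 cells in CM at 16 h differed from those in control medium by a small set of genes, clock genes among them. Per3 (0.87 ± 0.07) and Per2 (0.75 ± 0.07) rose. The activator gene Arntl (ENSMUSG00000055116; chromosome 7, 113207465 to 113314126, plus strand) fell (-1.14 ± 0.07), from 17.6 ± 0.742 to 8.02 ± 0.474 CPM. The acute-phase genes Lcn2 (3.20 ± 0.41) and Serpina3n (2.79 ± 0.34) rose, both under 2 CPM on average, as did complement C3 (1.24 ± 0.14). The imprinted RNA H19 rose (1.32 ± 0.07) from 78.7 ± 5.36 to 197 ± 4.28 CPM, with the calcium channel Ryr1 (0.91 ± 0.21) and Angpt4 (0.87 ± 0.18). Decorin (Dcn, -1.05 ± 0.06), the secreted factor Stc1 (-1.05 ± 0.11), the incretin receptor Glp1r (-1.03 ± 0.16) and Cd53 (-1.0 ± 0.14) fell. The chemokine Ppbp (-0.92 ± 0.17), Ifitm1 (-0.80 ± 0.10) and Rgs16 (-0.77 ± 0.10) fell too.

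Of 14450 genes, 294 passed, 120 higher and 174 lower, and 16 changed at least 2-fold. Of 19 tested core clock genes, 9 rose and 2 fell (11 and 3 adjusted over the list alone, camera adjusted p = 1.26e-09, 0.0214 with estimated correlation). Dbp (0.70 ± 0.14), Tef (0.65 ± 0.04), Ciart (0.46 ± 0.12) and Nr1d2 (0.41 ± 0.05) rose. Per1 (0.41 ± 0.09), Cry1 (0.34 ± 0.07) and Bhlhe41 (0.33 ± 0.07) rose and Clock (-0.18 ± 0.05) fell. Nfil3 (-0.26 ± 0.07), Bhlhe40 (0.18 ± 0.06), Cry2 (0.25 ± 0.09) and Nr1d1 (0.13 ± 0.06) did not pass. Rora (0.52 ± 0.39), Npas2 (-0.49 ± 0.55) and Hlf (-0.07 ± 0.28) did not pass either. Troponin Tnnt2 rose (0.70 ± 0.06) in a sarcomere list that moved up (1 rose and 0 fell of 14, 5 and 1 adjusted over the list alone, camera adjusted p = 0.0147, 0.218 with estimated correlation). The matrix list moved up (7 rose and 2 fell of 35, 12 and 5 adjusted over the list alone, camera adjusted p = 0.0382, 0.614 with estimated correlation). Smooth muscle actin (Acta2, 0.39 ± 0.06) and Ccn2 (0.59 ± 0.09) rose in it and Col3a1 (-0.28 ± 0.04) fell. Mitotic genes moved down (0 rose and 4 fell of 30, 0 and 8 adjusted over the list alone, camera adjusted p = 6.85e-13, 0.128 with estimated correlation), with Aurkb at -0.19 ± 0.04 and Top2a at -0.19 ± 0.04. Of 20 tested glucocorticoid-responsive genes, 4 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0382, 0.614 with estimated correlation). Fkbp5 (0.34 ± 0.05) and Pdk4 (0.28 ± 0.06) rose and Errfi1 fell (-0.24 ± 0.05).

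Further lists passed camera at 16 h while holding few or no called genes. S phase moved up (0 rose and 0 fell of 30, 1 and 0 adjusted over the list alone, camera adjusted p = 0.0108, 0.614 with estimated correlation), as did glycolysis and hypoxia (0 rose and 0 fell of 28, the same adjusted over the list alone, camera adjusted p = 0.0382, 0.614 with estimated correlation). Cytosolic ribosomal proteins moved up (0 rose and 0 fell of 42, the same adjusted over the list alone, camera adjusted p = 0.0382, 0.669 with estimated correlation), as did endothelial markers (0 rose and 0 fell of 4, 1 and 0 adjusted over the list alone, camera adjusted p = 0.0382, 0.311 with estimated correlation). The stress response list moved down (1 rose and 1 fell of 30, the same adjusted over the list alone, camera adjusted p = 0.0382, 0.614 with estimated correlation). The direction of the ribosomal protein list turned to down without control 16 h replicate 2, so it is not settled. With an estimated correlation only the core clock kept its call. Leaving out 1 of the 8 libraries ended the calls of Ryr1 (1 case, adjusted p of 0.0754 without control 16 h replicate 2), Top2a (2 cases, adjusted p up to 0.0754 without control 16 h replicate 4) and Clock (5 cases, adjusted p up to 0.111 without CM 16 h replicate 4). Others lost in this way were Per1 (3 cases, adjusted p up to 0.0550 without CM 16 h replicate 4), Ciart (6 cases, adjusted p up to 0.149 without CM 16 h replicate 4) and Bhlhe41 (3 cases, adjusted p up to 0.0675 without control 16 h replicate 2). The fit of only 8 libraries ended those of Aurkb, Top2a, Ciart and Clock (adjusted p of 0.0527 to 0.0728). List calls lost without 1 library were endothelial markers (6 cases, adjusted p up to 0.205), glycolysis (5 cases, adjusted p up to 0.524), ribosomal proteins (5 cases, adjusted p up to 0.686), matrix (4 cases, adjusted p up to 0.215) and stress response (4 cases, adjusted p up to 0.132). Others were glucocorticoid-responsive genes (3 cases, adjusted p up to 0.221), sarcomere (1 case, adjusted p of 0.118) and S phase (1 case, adjusted p of 0.0548). RLE size factors ended the calls of glycolysis, matrix and ribosomal proteins (adjusted p = 0.0516 each), and no filter those of the stress response (adjusted p = 0.0883) and endothelial markers (adjusted p = 0.885). Replicate 3 of the 16 h controls stood furthest from its group, with a chi-square per degree of freedom of 8.05 to 16.6 against 2.73 to 5.58 among the other 3. Without it 280 genes passed. The CM libraries of 16 h were deeper than the controls, so counts were thinned to equal totals, an alternative chosen after seeing the data. Then 294 genes and 6 lists passed. Glycolysis (adjusted p = 0.0597), matrix (adjusted p = 0.0562), ribosomal proteins (adjusted p = 0.0630) and the glucocorticoid-responsive list did not (for the last 0.0630, against 0.0188 to 0.0451 with other scaling, without a filter or with a block).

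At 28 h HL-1 cells in CM had lower inflammatory genes. Of 21 tested chemokines and NF-kB targets, 0 rose and 9 fell (0 and 11 adjusted over the list alone, camera adjusted p = 1.51e-16, 0.000453 with estimated correlation). Ptgs2 (-0.53 ± 0.05), Ccl2 (-0.63 ± 0.08), Ccl7 (-0.63 ± 0.08) and Cxcl1 (-0.38 ± 0.05) were among them. The largest falls were in the chemokine Ccl3 (-1.58 ± 0.26), the interleukin receptor Il1rl1 (-1.55 ± 0.31), the neuropeptide Y receptor Npy1r (-1.51 ± 0.20) and the ATP-gated channel P2rx1 (-1.38 ± 0.30). The cytokine Il1a (-1.33 ± 0.25), Sprr2h (-1.22 ± 0.30), Dcn (-1.06 ± 0.06) and the Wnt antagonist Sfrp4 (-1.03 ± 0.10) fell next. Smoc2 (1.48 ± 0.28), endothelin (Edn1, 0.98 ± 0.20), H19 (0.94 ± 0.06) and the metalloprotease Adam12 (0.84 ± 0.10) rose most. Titin (Ttn, 0.69 ± 0.16), the actin-binding Coro6 (0.68 ± 0.09), C3 (0.67 ± 0.07) and Tnnt2 (0.65 ± 0.06) followed.

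Here 278 genes passed, 102 higher and 176 lower, with 11 changed at least 2-fold. Clock genes called at both times had the opposite sign to 16 h. Per2 (-0.91 ± 0.08), Per3 (-0.62 ± 0.07), Cry1 (-0.61 ± 0.08), Tef (-0.45 ± 0.04) and Nr1d2 (-0.28 ± 0.05) fell and Arntl rose (0.25 ± 0.05). The list moved down (1 rose and 5 fell of 19, 2 and 8 adjusted over the list alone, camera adjusted p = 1.15e-05, 0.0791 with estimated correlation). Cry2 (-0.34 ± 0.09), Dbp (-0.56 ± 0.17), Npas2 (1.06 ± 0.33), Hlf (-1.04 ± 0.40), Bhlhe41 (-0.11 ± 0.07) and Rora (-0.26 ± 0.18) did not pass. Ciart (-0.17 ± 0.12), Per1 (-0.07 ± 0.09), Bhlhe40 (-0.02 ± 0.05), Nfil3 (-0.02 ± 0.06), Nr1d1 (0.0038 ± 0.07) and Clock (-0.0024 ± 0.05) did not pass either. The sarcomere list moved up (2 rose and 0 fell of 14, the same adjusted over the list alone, camera adjusted p = 0.00275, 0.134 with estimated correlation). Matrix genes moved up (5 rose and 2 fell of 35, 11 and 4 adjusted over the list alone, camera adjusted p = 3.96e-05, 0.264 with estimated correlation). Thbs1 (0.28 ± 0.03), the crosslinking enzyme Lox (0.22 ± 0.03) and Acta2 (0.32 ± 0.06) rose and Col3a1 fell (-0.28 ± 0.04). Immediate early genes moved down (1 rose and 3 fell of 25, 1 and 5 adjusted over the list alone, camera adjusted p = 0.00591, 0.443 with estimated correlation), with the nuclear receptors Nr4a2 at -0.83 ± 0.08 and Nr4a3 at -0.87 ± 0.21. Fkbp5 rose (0.26 ± 0.05), but the glucocorticoid-responsive list did not pass (2 rose and 3 fell of 20, 2 and 4 adjusted over the list alone, camera adjusted p = 0.616). The growth factor Hgf (-0.47 ± 0.06) and Igfbp4 (-0.52 ± 0.08) fell.

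The remaining lists past camera at 28 h moved down, except hepatocyte genes, which moved up (1 rose and 0 fell of 5, 2 and 0 adjusted over the list alone, camera adjusted p = 0.0332, 0.167 with estimated correlation). They were S phase (0 rose and 3 fell of 30, 0 and 5 adjusted over the list alone, camera adjusted p = 4.25e-09, 0.264 with estimated correlation) and the stress response (0 rose and 1 fell of 30, the same adjusted over the list alone, camera adjusted p = 0.000588, 0.230 with estimated correlation). Nuclear-encoded oxidative phosphorylation (0 rose and 0 fell of 36, the same adjusted over the list alone, camera adjusted p = 0.000588, 0.430 with estimated correlation) and mitochondrially encoded mRNAs (0 rose and 0 fell of 12, 0 and 2 adjusted over the list alone, camera adjusted p = 0.00775, 0.429 with estimated correlation) were also down. So were ribosome biogenesis (0 rose and 2 fell of 24, the same adjusted over the list alone, camera adjusted p = 0.00156, 0.443 with estimated correlation) and autophagy (0 rose and 2 fell of 25, 1 and 4 adjusted over the list alone, camera adjusted p = 0.00775, 0.167 with estimated correlation). Without control replicate 1 of 28 h, 179 genes passed, and without CM replicate 3 of 28 h, 170, against 278 with all libraries. Leaving out 1 library ended the calls of Ttn (4 cases, adjusted p up to 0.0841 without CM 28 h replicate 4) and P2rx1 (3 cases, adjusted p up to 0.0730 without control 28 h replicate 1). Others lost in this way were Sprr2h (6 cases, adjusted p up to 0.0977 without control 28 h replicate 3) and Nr4a3 (6 cases, adjusted p up to 0.102 without CM 28 h replicate 1). List calls lost in this way were hepatocyte genes (4 cases, adjusted p up to 0.0741), immediate early genes (1 case, adjusted p of 0.115), autophagy (1 case, adjusted p of 0.0734), mitochondrially encoded mRNAs (1 case, adjusted p of 0.0673) and ribosome biogenesis (1 case, adjusted p of 0.0673). The hepatocyte call also ended with no filter (adjusted p = 0.299) and thinned counts (adjusted p = 0.0688).

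**Figure D3:**
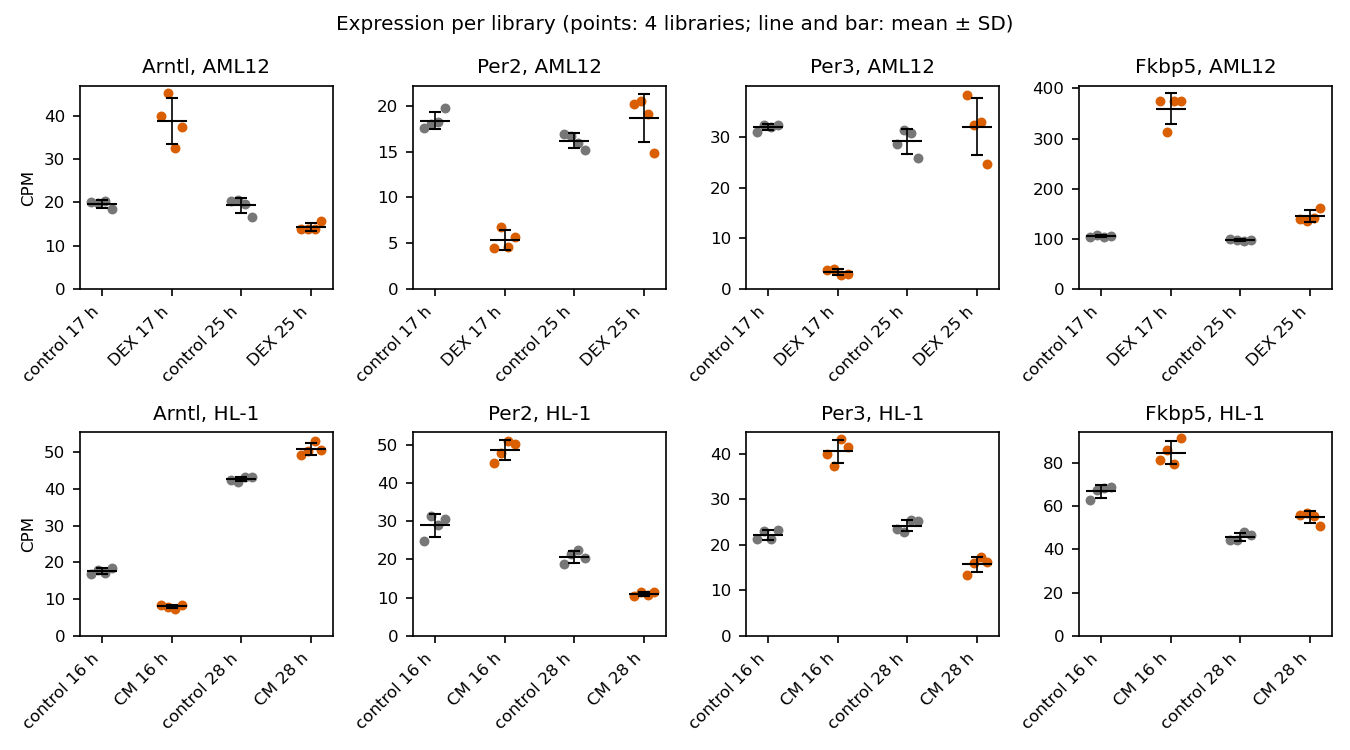
Expression in CPM of Arntl, Per2, Per3 and Fkbp5 in each library of AML12 (top) and HL-1 (bottom), by group, with points for the 4 libraries and a line and bar for mean ± SD. Arntl averaged 17.6 ± 0.742 CPM in HL-1 controls and 8.02 ± 0.474 CPM in CM at 16 h.

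The CM effect in HL-1 cells differed between the times for 40 genes, 15 with a more positive effect at 28 h and 25 with a more negative one. Arntl (1.39 ± 0.08) had the former. Per2 (-1.66 ± 0.11), Per3 (-1.49 ± 0.10), Dbp (-1.25 ± 0.22), Tef (-1.11 ± 0.06), Cry1 (-0.95 ± 0.10), Nr1d2 (-0.69 ± 0.07) and Cry2 (-0.58 ± 0.13) had the latter. The clock list moved down (camera adjusted p = 2.05e-15, 0.00226 with estimated correlation). The plasminogen activator Plat (0.76 ± 0.10), Tinagl1 (0.66 ± 0.13) and Dusp27 (0.56 ± 0.12) had a more positive effect at 28 h. Lcn2 (-2.99 ± 0.53), Serpina3n (-2.29 ± 0.42), Ptgs2 (-0.52 ± 0.07), Cxcl1 (-0.53 ± 0.08) and Nr4a2 (-0.55 ± 0.11) had a more negative one. The inflammatory list moved down (camera adjusted p = 7.29e-11, 0.00226 with estimated correlation). So did the acute-phase list (camera adjusted p = 9.94e-06, 0.0216 with estimated correlation).

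Of the lists, 14 of 34 passed camera, 3 of them with an estimated correlation. Bhlhe41 (-0.44 ± 0.10), Per1 (-0.48 ± 0.12), Ciart (-0.62 ± 0.17), Clock (0.18 ± 0.06) and Bhlhe40 (-0.20 ± 0.07) did not pass. Nfil3 (0.24 ± 0.09), Npas2 (1.56 ± 0.65), Hlf (-0.97 ± 0.49), Rora (-0.78 ± 0.43) and Nr1d1 (-0.13 ± 0.09) did not pass either. Without the low-count filter 97 genes passed this test, and with DESeq2 68. Without 1 of the 16 libraries the lost calls were those of Tinagl1 (2 cases, adjusted p up to 0.0607 without control 28 h replicate 1) and Dusp27 (7 cases, adjusted p up to 0.0753 without control 28 h replicate 3). Others lost in this way were Nr4a2 (6 cases, adjusted p up to 0.0888 without CM 16 h replicate 4) and Cry2 (13 cases, adjusted p up to 0.168 without CM 16 h replicate 4). The call of Cry2 also ended with limma-voom (adjusted p = 0.0564) and thinned counts (adjusted p = 0.0972). In HL-1 cells 107 genes passed at both times, against 5.66 for independent lists. Of these, 95 had the same sign and 12 opposite signs. All 6 clock genes among them (Arntl, Cry1, Nr1d2, Per2, Per3 and Tef) had opposite signs. Across genes the correlation of both effects was 0.207 (Pearson) and 0.224 (Spearman).

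Between 16 h and 28 h HL-1 controls changed widely. Of 28 tested glycolysis and hypoxia genes, 28 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 8.61e-23, 0.0109 with estimated correlation), with Ndrg1 at 2.94 ± 0.05 and the oxidase Ero1a at 2.98 ± 0.05. Of 24 tested ribosome biogenesis genes, 0 rose and 24 fell (the same adjusted over the list alone, camera adjusted p = 1.65e-18, 0.0275 with estimated correlation), with Ddx21 at -1.24 ± 0.04 and Dkc1 at -1.60 ± 0.05. S phase genes were lower (0 rose and 29 fell of 30, the same adjusted over the list alone, camera adjusted p = 1.70e-15, 0.0695 with estimated correlation), as Mcm10 (-1.32 ± 0.06) and Mcm2 (-1.12 ± 0.05). Mitotic genes were lower (0 rose and 30 fell of 30, the same adjusted over the list alone, camera adjusted p = 5.57e-18, 0.0160 with estimated correlation), as Aurka (-0.98 ± 0.04). Heat shock genes were lower (2 rose and 13 fell of 17, the same adjusted over the list alone, camera adjusted p = 1.59e-05, 0.0703 with estimated correlation), as Hsph1 (-1.83 ± 0.07) and Hspd1 (-1.10 ± 0.05). Acute-phase genes were higher (9 rose and 0 fell of 10, the same adjusted over the list alone, camera adjusted p = 8.08e-06, 0.0145 with estimated correlation), as Cp (2.03 ± 0.04) and C3 (4.14 ± 0.11). NF-kB targets were higher (16 rose and 1 fell of 21, the same adjusted over the list alone, camera adjusted p = 1.62e-07, 0.0109 with estimated correlation), as Nfkbiz (1.90 ± 0.05) and Cxcl1 (1.75 ± 0.05). Matrix genes were higher (29 rose and 5 fell of 35, the same adjusted over the list alone, camera adjusted p = 6.72e-09, 0.0695 with estimated correlation), as Lox (1.54 ± 0.04). Over the 4 libraries of each time, the nitric oxide synthase Nos2 went from 1 to 3281 counts (ratio 3231, 579.6 to 127674), a ratio of CPM given with its 95% counting interval. Sectm1a went from 1 to 76 counts (ratio 74.9, 13.0 to 2995) and the immune regulator Aire from 3 to 134 counts (ratio 44.0, 14.7 to 216). Selenbp1 rose (4.87 ± 0.16), while Gsta1 (-3.62 ± 0.33), Tmem179 (-2.82 ± 0.45), Dok3 (-2.26 ± 0.37) and Gsta2 (-2.20 ± 0.30) fell.

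In CM, glycolysis and hypoxia genes rose (28 rose and 0 fell of 28, the same adjusted over the list alone, camera adjusted p = 5.24e-21, 0.0219 with estimated correlation). Ribosome biogenesis genes fell (0 rose and 24 fell of 24, the same adjusted over the list alone, camera adjusted p = 9.68e-18, 0.0383 with estimated correlation). S phase (0 rose and 29 fell of 30, the same adjusted over the list alone, camera adjusted p = 1.54e-16, 0.0634 with estimated correlation) and mitotic genes (0 rose and 30 fell of 30, the same adjusted over the list alone, camera adjusted p = 1.08e-14, 0.0383 with estimated correlation) were lower. Ndrg1 (2.85 ± 0.05), Ero1a (3.01 ± 0.05), Lox (1.87 ± 0.04), Cp (2.11 ± 0.04) and C3 (3.57 ± 0.09) rose. Ddx21 (-1.35 ± 0.04), Nolc1 (-1.46 ± 0.05), Mcm2 (-1.33 ± 0.05) and Aurka (-0.96 ± 0.04) fell. Gsta1 (-2.93 ± 0.30), Gsta2 (-2.22 ± 0.31), the phospholipase Pla2g4c (-2.61 ± 0.21) and Lsmem2 (-2.43 ± 0.37) fell most. Nos2 went from 3 to 3541 counts (ratio 1201, 411 to 5827) and Aire from 2 to 219 counts (ratio 111, 30.5 to 926). Selenbp2 went from 1 to 87 counts (ratio 88.5, 15.5 to 3536) and Ccl3 from 1 to 78 counts (ratio 79.4, 13.8 to 3174). In all 9071 genes passed in controls (4550 higher and 4521 lower at 28 h) and 9453 in CM (4706 higher and 4747 lower). For controls 19 of 34 lists passed camera, 9 of them with an estimated correlation, and for CM cells 18 of 34 lists passed camera, 7 of them with an estimated correlation.

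From 16 h to 28 h clock genes of control HL-1 cells moved both ways. Bhlhe40 (1.85 ± 0.05), Arntl (1.28 ± 0.06), Nfil3 (1.26 ± 0.07) and Rora (3.49 ± 0.27) rose. Bhlhe41 (0.85 ± 0.07), Per1 (0.54 ± 0.09), Cry2 (0.24 ± 0.09) and Ciart (0.28 ± 0.12) rose as well. Nr1d2 (-0.72 ± 0.05), Tef (-0.47 ± 0.04), Per2 (-0.48 ± 0.07) and Clock (-0.18 ± 0.05) fell. Cry1 (-0.27 ± 0.07), Nr1d1 (-0.24 ± 0.07), Dbp (-0.54 ± 0.15) and Hlf (-0.94 ± 0.32) fell as well. Npas2 (1.0 ± 0.45) and Per3 (0.12 ± 0.07) did not pass. In CM cells Arntl (2.66 ± 0.06), Bhlhe40 (1.65 ± 0.05) and Nfil3 (1.5 ± 0.07) rose. Rora (2.71 ± 0.25), Npas2 (2.56 ± 0.40) and Bhlhe41 (0.42 ± 0.07) rose as well. Tef (-1.57 ± 0.04), Nr1d2 (-1.41 ± 0.05), Per2 (-2.14 ± 0.08), Per3 (-1.37 ± 0.07) and Cry1 (-1.22 ± 0.07) fell. Dbp (-1.79 ± 0.15), Nr1d1 (-0.36 ± 0.06), Hlf (-1.91 ± 0.35), Cry2 (-0.34 ± 0.09) and Ciart (-0.35 ± 0.11) fell as well. Per1 (0.06 ± 0.09) and Clock (0.0021 ± 0.05) did not pass. In controls, the calls lost without 1 of the 8 libraries were those of Cry2 (2 cases, adjusted p up to 0.102 without control 16 h replicate 4), Hlf (1 case, adjusted p of 0.0565 without control 28 h replicate 4) and Ciart (6 cases, adjusted p up to 0.143 without control 16 h replicate 1). That of Ciart also ended with no filter, the block, limma-voom and only 8 libraries (adjusted p of 0.0540 to 0.0622). Gsta1 and Gsta2, and Selenbp1 and Selenbp2, are near-identical pairs whose reads the counting could split. A harvest effect is not separable from time here either.

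The responses of both lines were set side by side over 12272 genes tested in each, taking calls at either time. Genes lower in both numbered 76 against 40.0 for independent lists (odds ratio 2.44, 95% interval 1.81 to 3.27). Fisher's exact test, two-sided, gave p = 4.51e-09 (adjusted p = 6.02e-09 over 4 tests). Genes higher in both numbered 42 against 33.7 (odds ratio 1.35, 0.920 to 1.96, adjusted p = 0.112). Opposite directions were also more frequent than for independent lists. There were 73 genes lower in AML12 and higher in HL-1 against 26.9 (odds ratio 4.59, adjusted p = 1.19e-17). There were 92 higher in AML12 and lower in HL-1 against 50.03 (odds ratio 2.52, adjusted p = 3.21e-10). Without the low-count filter the odds ratio for genes higher in both was 2.38 (Fisher's exact test, p = 8.81e-09). A gene called at both times with opposite signs, such as a clock gene, counts in both directions.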

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

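All tests of the patterns weighed in this part, on the signs of clock genes and on replicate 4 of DEX at 25 h, were chosen after the results were seen, and a first test of depth by thinning, with 6 clock genes kept in each line, was replaced as it could hardly turn a sign. Core clock genes called at both times moved in opposite directions in both lines: 6 of 8 in AML12 and 6 of 6 in HL-1. If treated and control libraries had been exchanged at one time, most other genes would turn too, but 94.6% of 1313 others in AML12 (93.2% to 95.8%) and 94.1% of 101 in HL-1 (87.5% to 97.8%) had the same sign at both times. The log2 ratio of treated to control totals changed between the times by at most 0.173 in AML12 and 0.197 in HL-1 (95% intervals). The effects of these clock genes changed by at least 0.510 and 0.556 (lowest 95% limits), which argues against depth. A shift of clock phase in treated cells is a hypothesis for the signs, untested because 2 times give no phase. An unrecorded harvest difference stays open.

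Single libraries stood apart where their gap to the nearest other library, divided by the range of the 4, passed Dixon's 95% critical value. This happened in 62 of 748 groups of 4 examined (8.29%), where chance gives about 1 in 20 (5%). Replicate 4 of DEX at 25 h in AML12 held 14 of these, followed by replicate 2 of DEX at 17 h with 6 and replicate 1 of HL-1 control at 16 h with 6.

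Over 376 genes at least 2-fold apart between the DEX groups, that replicate 4 lay a median 13.3% of the way from the other 25 h libraries to the 17 h mean (median absolute deviation 14.1), which excludes a label exchanged with a 17 h library. A share of 17 h RNA in it beside other causes remains possible and cannot be told apart from them. In a first version the shift was 9.85% for 181 genes higher at 17 h, 18.1% for 195 higher at 25 h and 9.74% for 8 glucocorticoid-responsive genes. In a second, with the best common share at 10.9%, 1.60% of 376 genes (6) lay over 3 SD from that level, and 0 did in each of the other 3 libraries. Single genes differed, with Zbtb16 0.837%, Sgk1 0.739%, Sult1a1 28.8% and Nr1d1 -59.0% of the way, and a delayed or different culture was not tested.

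The values that stood apart are given with the mean of the other 3 libraries of the group, and for genes both are in CPM. Total counts of HL-1 control replicate 3 at 28 h were 18.1 M against 16.1 M. In AML12 control 17 h these were Clca3b at 15.9 in replicate 4 against 14.2, Cry2 at 20.5 in replicate 3 against 18.1, Dhcr7 at 59.0 in replicate 3 against 63.4 and Endou at 1.16 in replicate 1 against 0.798. Insig1 at 108 in replicate 4 against 102 and Mcm3 at 91.0 in replicate 1 against 81.0 lay apart too. In AML12 DEX 17 h these were Als2cr12 at 2.79 in replicate 2 against 1.85, Ccl3 at 0.0610 in replicate 3 against 0, Ccl5 at 0.185 in replicate 4 against 0.0616 and Chst4 at 0.976 in replicate 3 against 0.721. Fkbp5 at 314 in replicate 2 against 375, Gabrp at 4.56 in replicate 2 against 3.12, Herpud1 at 304 in replicate 2 against 255 and Serping1 at 1.01 in replicate 2 against 0.509 lay apart too. Uroc1 at 0.444 in replicate 2 against 0.183 did as well. In AML12 control 25 h these were Apol8 at 0.174 in replicate 4 against 0.0632, Ppara at 1.01 in replicate 1 against 1.16 and Vcam1 at 239 in replicate 1 against 265. In AML12 DEX 25 h these were Alb at 3.66 in replicate 4 against 1.91, Arntl at 15.8 in replicate 4 against 13.9, Ccl20 at 128 in replicate 4 against 155 and Ccl3 at 0.183 in replicate 4 against 0.495. Chad at 4.29 in replicate 3 against 5.03, Cnn1 at 5.37 in replicate 4 against 11.2, Egr1 at 10.5 in replicate 4 against 15.2 and Gabrp at 9.89 in replicate 4 against 16.8 lay apart too. Nr1d1 at 52.5 in replicate 4 against 36.8, Ppara at 2.81 in replicate 4 against 1.44, Psat1 at 417 in replicate 4 against 335 and Rrm2 at 104 in replicate 4 against 78.0 did as well. Sult1a1 at 4.46 in replicate 4 against 1.61, Tm7sf2 at 65.4 in replicate 4 against 58.3 and Tnc at 15.6 in replicate 4 against 24.5 did as well.

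In HL-1 control 16 h these were Cp at 167 in replicate 1 against 155, Cry2 at 11.0 in replicate 4 against 13.2, Dusp27 at 11.7 in replicate 1 against 10.2 and Nos2 at 0.0569 in replicate 1 against 0. Per1 at 20.0 in replicate 1 against 24.8, Rgs16 at 6.55 in replicate 4 against 8.66, Ryr1 at 0.751 in replicate 2 against 1.08 and Sectm1a at 0.0645 in replicate 3 against 0 lay apart too. Selenbp2 at 0.114 in replicate 1 against 0 and Tinagl1 at 33.6 in replicate 1 against 45.5 did as well. In HL-1 CM 16 h these were Aurka at 169 in replicate 4 against 174, Ccl3 at 0.0533 in replicate 3 against 0, Ero1a at 174 in replicate 2 against 200.3 and Lcn2 at 0.981 in replicate 1 against 2.20. Ndrg1 at 94.5 in replicate 2 against 104, Selenbp2 at 0.0545 in replicate 2 against 0, Sprr2h at 0.506 in replicate 4 against 0.141 and Tmem179 at 1.20 in replicate 2 against 0.768 lay apart too. Ttn at 9.76 in replicate 1 against 6.43 did as well. In HL-1 control 28 h these were Aurka at 89.4 in replicate 1 against 97.2, Ciart at 7.57 in replicate 2 against 10.4 and Edn1 at 1.70 in replicate 4 against 1.25. In HL-1 CM 28 h these were C3 at 119 in replicate 4 against 108, Ccn2 at 13.5 in replicate 3 against 11.3, Cd53 at 4.87 in replicate 2 against 4.14 and Lcn2 at 2.10 in replicate 4 against 1.41. Pdk4 at 58.3 in replicate 1 against 53.1 and Plat at 83.1 in replicate 3 against 73.3 lay apart too.

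The DEX effect in AML12 differed between the times, by edgeR's test of the difference with an adjusted p under 0.05, for 54 of the genes whose DEX effects or their difference the report gives for AML12. Each is given as the log2 effect at 25 h minus that at 17 h, with both effects (17 h to 25 h). The differences were Sstr3 -4.26 (3.59 to -0.67), Sult1a1 -3.64 (5.07 to 1.43), Kif17 -3.56 (4.41 to 0.85), Extl1 -3.18 (2.40 to -0.78), Orm1 -2.76 (3.67 to 0.91) and Ppara -2.34 (3.00 to 0.66). Next came Sgk1 -2.32 (2.32 to -0.0023), Cryaa -2.04 (3.25 to 1.21), Crispld2 -1.96 (3.66 to 1.70), Nr1h4 -1.76 (2.01 to 0.25), Ctgf -1.70 (1.80 to 0.10) and Tsc22d3 -1.53 (1.73 to 0.20). Then came Arntl -1.40 (0.97 to -0.42), Per1 -1.39 (1.65 to 0.26), Fkbp5 -1.21 (1.77 to 0.56), Klf9 -1.14 (1.23 to 0.09), Fam107a -1.02 (2.10 to 1.07) and Hp -0.92 (1.55 to 0.63). Next came Egr1 -0.85 (0.25 to -0.60), Atf4 -0.71 (0.63 to -0.08), Nfil3 -0.68 (0.33 to -0.35), Herpud1 -0.68 (0.73 to 0.05), Rrm2 -0.67 (1.59 to 0.92) and Psat1 -0.62 (1.10 to 0.48). Then came Asns -0.53 (0.87 to 0.35), Msmo1 -0.48 (0.65 to 0.17), Lss -0.38 (0.62 to 0.24), Cdkn1a -0.31 (-0.13 to -0.44), Clock -0.24 (0.31 to 0.07) and Phlda3 -0.23 (-0.14 to -0.37). Next came Jun 0.36 (-0.73 to -0.37), Irf1 0.59 (-0.68 to -0.09), Hnf4a 0.64 (-0.54 to 0.10), Cry1 0.66 (-1.01 to -0.35), Hpx 0.86 (-1.52 to -0.66) and Agt 0.93 (-2.12 to -1.18). Then came Ptgs2 0.98 (-1.64 to -0.65), Cry2 0.99 (-1.02 to -0.03), Blk 1.23 (-2.79 to -1.56), Gbp2 1.32 (-1.5 to -0.18), Cxcl5 1.39 (-1.5 to -0.11) and Clca3b 1.56 (-3.97 to -2.41). Next came Nr1d1 1.64 (-0.95 to 0.69), Nr1d2 1.84 (-1.63 to 0.22), Per2 1.98 (-1.77 to 0.21), Gabrp 2.12 (-3.09 to -0.98), Chst4 2.31 (-2.91 to -0.60) and Ccl20 2.42 (-2.24 to 0.18). Then came Vwa5b1 2.51 (-2.83 to -0.32), Myh15 2.84 (-3.19 to -0.36), Tef 3.26 (-2.75 to 0.51), Per3 3.36 (-3.22 to 0.14), Ccl3 3.38 (-4.71 to -1.33) and Dbp 4.55 (-3.88 to 0.66).

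In HL-1 the CM effect differed in the same test for 19 of the genes whose CM effects or their difference the report gives, each written as 28 h minus 16 h with both effects (16 h to 28 h). The differences were Lcn2 -2.99 (3.20 to 0.20), Serpina3n -2.29 (2.79 to 0.5), Per2 -1.66 (0.75 to -0.91), Per3 -1.49 (0.87 to -0.62), Dbp -1.25 (0.70 to -0.56) and Tef -1.11 (0.65 to -0.45). Next came Cry1 -0.95 (0.34 to -0.61), Ccl7 -0.70 (0.07 to -0.63), Nr1d2 -0.69 (0.41 to -0.28), Ccl2 -0.68 (0.05 to -0.63), Cry2 -0.58 (0.25 to -0.34) and Nr4a2 -0.55 (-0.29 to -0.83). Then came Cxcl1 -0.53 (0.15 to -0.38), Ptgs2 -0.52 (-0.02 to -0.53), Lox 0.33 (-0.12 to 0.22), Dusp27 0.56 (-0.32 to 0.24), Tinagl1 0.66 (-0.48 to 0.19) and Plat 0.76 (-0.39 to 0.36). Next came Arntl 1.39 (-1.14 to 0.25).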

How the results depend on the processing

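Thinning to the lowest total and the strata of expression were chosen after the data were seen, while all other alternatives in this part were planned. Of the 811 called results that the rule for single genes gave, 741 kept their call under every alternative in which they were tested. The other 70 lost it under at least 1, 66 of them on leaving out a library, and 0 changed sign. Calls kept were 808 of 811 with RLE size factors, 800 with total counts only, 802 with no filter and 804 with limma-voom. DESeq2 kept 795 of 802 with an adjusted p, the fit of 8 libraries 702 of 715, and thinned counts 800 of 810. Leaving out 1 library kept 6916 of 7208.

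The number of changed genes stayed within 1.5 times the reported one in all comparisons and planned settings but these. For the difference of the CM effect between the times in HL-1, 40 genes became 97 with no filter and 68 with DESeq2. For CM at 28 h, 278 genes became 179 without control replicate 1 and 170 without CM replicate 3. On leaving out 1 library the counts ranged from 4812 to 5569 (DEX, 17 h), 1135 to 1607 (DEX, 25 h), 202 to 280 (CM, 16 h) and 170 to 334 (CM, 28 h). The ranges were 1962 to 2657 and 32 to 55 for the differences in AML12 and HL-1. Over time they were 5486 to 5709 in AML12 controls, 7386 to 8104 in DEX cells, 8596 to 8888 in HL-1 controls and 8968 to 9208 in CM cells. The causes were not tested. Total counts as the only scaling moved the share of higher calls by over 10 points in the AML12 difference (48.9% to 62.2%) and over time in AML12 controls (50.8% to 39.5%). With the 8 compared libraries only, that share at 28 h moved from 36.7% to 46.8%. For the difference in HL-1 it moved from 37.5% to 48.6% without CM 16 h replicate 2, and to the same share without replicate 3. No scaling moved the median log2 fold change of all genes by over 0.1.

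The replicate numbers paired the libraries weakly at most. Deviations from the group mean of same-numbered libraries had a median correlation of 0.00350 (-0.0945 to 0.108) in AML12 and 0.0172 (-0.119 to 0.121) in HL-1. In 7 and 12 of 24 comparisons of a library with the 4 of another group, the same number correlated best, where chance gives 1 in 4. With the replicate block 5369 and 1633 genes were called for DEX at the earlier and later time, and 295 and 294 for CM. The block gave 2208 and 49 genes for the differences, 6095 and 7889 over time in AML12, and 9081 and 9483 in HL-1. It kept 806 of 811 called results of the rule.

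Of 137 list calls, 133 were kept with RLE size factors, 129 with no filter, 137 with the block and 128 with thinned counts. Leaving out 1 library kept 1210 of 1296, an estimated correlation 34 and fry 113 of 137. The number of lists called depended on the list test. An estimated correlation called 4, 5, 4, 0 and 0 lists in AML12, for the 17 h and 25 h effects of DEX, their difference, and control and DEX cells over time. In HL-1 it called 1, 1, 3, 9 and 7 for the 16 h and 28 h effects of CM, their difference, and control and CM cells over time. Fry, which asks another question, called 23, 21, 15, 27 and 29 lists in AML12. It called 4, 11, 4, 30 and 31 in HL-1, in the same orders. For CM at 16 h thinned counts called 6 lists. Leaving out 1 library there called 4 to 10, with 4 without control replicate 1 and 6 without CM replicate 2 or 4. The list of cytosolic ribosomal proteins turned its direction there on leaving out 1 library (adjusted p of 0.000795 to 0.686), and the cause was not tested.

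Among the genes named in the text, the other sign changes were in clock genes that were not called, and the cause was not tested. In HL-1 at 28 h, Clock was at 0.00855 with total counts only, 0.0106 with 8 libraries and 0.0138 with thinned counts. Thinned counts put Nfil3 at 0.0137 and Bhlhe40 at 0.00166 there, and no filter put Clock in CM cells over time at -0.0224. Leaving out 1 library gave ranges, at 25 h in AML12, of -0.105 to 0.0112 for Cry2 and -0.114 to 0.0867 for Ciart. The range of Bhlhe40 in the AML12 difference was -0.0176 to 0.106. Over time in AML12 controls, Arntl ranged from -0.0621 to 0.0385, Dbp from -0.0290 to 0.142 and Bhlhe41 from -0.0730 to 0.0485. For CM at 16 h Hlf ranged from -0.232 to 0.0563. For CM at 28 h the ranges were -0.0362 to 0.0326 for Clock, -0.0367 to 0.0394 for Nr1d1, -0.0479 to 0.00829 for Nfil3 and -0.0624 to 0.0199 for Bhlhe40. In CM cells over time they were -0.0321 to 0.0405 for Clock and -0.00333 to 0.111 for Per1.

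The overlap of genes higher in both lines, with an odds ratio of 1.35, reached 2.38 with no filter, where untested low genes enter the background. Within 10 strata of expression the odds ratio was 1.12 for genes higher in both and 2.26 for genes lower in both. It was 4.27 for genes lower in AML12 and higher in HL-1, and 2.06 for the reverse. At the real depth with 4 libraries per group, in the simulations of CM at 16 h, 63 of 97 tested genes with a log2 change of 0.5 were found, so such effects can be missed. Depth and the number of libraries were not varied.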

Other observations

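In this part the test of carry-over on all AML12-specific genes was chosen after the result was seen, while the tests on the 2 gene lists and on the splits of the libraries were planned. HL-1 cells in CM may respond to the synchronising agent or its effect carried over in the medium, and the planned test asked for a rise of the glucocorticoid-responsive list by camera. It rose at 16 h (adjusted p = 0.0382), but with an estimated correlation the adjusted p was 0.614, with fry 0.245 and with thinned counts 0.0630. RLE size factors gave 0.0451, no filter 0.0188 and the replicate block 0.0439. The call held in 5 of 8 cases of leaving out 1 library (0.0175 to 0.221). It was lost without control replicate 1 (0.221), CM replicate 2 (0.134) or CM replicate 4 (0.0713).

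At 28 h the list did not rise (adjusted p = 0.616, direction down). Of 17 members that rose with DEX in AML12 at 17 h, 12 were tested in HL-1. There 3 rose at 16 h (Fkbp5, Lcn2, and Tsc22d3 at 0.31) and 1 fell, median log2 fold change 0.04. At 28 h 1 rose (Fkbp5) and 1 fell, median 0.06. The criterion was met but rests on the preset correlation and single libraries, so this stays a hypothesis.

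AML12 RNA carried over with the medium is another explanation for genes that rose in CM. For the 5 hepatocyte-list genes at 10 CPM or more in AML12 and under 1 CPM in HL-1 controls, the larger median log2 fold change of both times was 0.51, with a median absolute deviation of 1.40, too few counts to decide. The 36 genes at 100 CPM or more in AML12 and under 0.1 CPM in HL-1 controls reached 0.00856% and 0.0156% of their AML12 level in CM at 16 h and 28 h, against 0.00855% and 0.0127% in controls. The log2 ratio of CM to control was 0.01 (-0.54 to 0.56) and 0.29 (-0.13 to 0.72), with 95% counting intervals. This argues against carry-over in CM above that in controls at a level that would matter, by a criterion that was rewritten once after its first result; the first used the ratio and led to the same reading. The controls received medium of AML12 cells too, and the genes were chosen for low levels in controls, so a carry-over equal in both media was not tested.

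Other splits of the libraries into equal groups were tested for chance. With DEX at 17 h the real split of 8 libraries called 4825 genes, and 1 of 35 splits, the real one, called as many (highest other 0). At 25 h it called 1961 (1 of 35, highest other 1). Over time it called 6902 in AML12 controls (1 of 35, highest other 1) and 7137 in DEX cells (1 of 35, highest other 0). For CM at 28 h it called 308 (1 of 35, highest other 0), and over time 8866 in HL-1 controls (1 of 35, highest other 0) and 9249 in CM cells (1 of 35, highest other 0). For CM at 16 h it called 205 genes (1 of 35), the highest other 179, and 3 others called any. This points to structure beyond the medium, so chance stays open there. Other splits mix both groups, so chance is open for other counts.

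For the differences of effects 100 splits were drawn. In AML12 4 of 100 called as many genes as the real one (2283, highest other 4064), and in HL-1 4 of 100 did (40, highest other 186). The 3 others as large in each line were among 9 splits keeping both groups of one time whole, which carry real effects. Splits keeping neither time whole called at most 1 gene in AML12 and 2 in HL-1. They mix treated and control cells, so chance is not excluded.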
